A study of Homo sapiens with 5 samples.

How the data were processed

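SMAD2-bound DNA was recovered by chromatin immunoprecipitation from T47D cells with an antibody against SMAD2, and sequenced after preparation with an Ion Torrent fragment library kit and PCR, per the labels' protocols. The series holds 5 samples: 2 libraries from cells given activin A, 2 libraries from cells given palbociclib and then activin A, and 1 input library of genomic DNA from untreated cells that served as the control for peak calling. The input library has no processed file among those analysed here. Per the submitters' processing notes, Bowtie 1.1.0, Picard and MACS2 2.0.9 were used, with the genome build hg19. The order of these steps, read filters, duplicate handling and other parameters are not given in the sources used here. Each deposited file lists the peak summits of 1 library as single-base positions, so the authors called peaks in each library and not on pooled replicates. Each summit carries a score, which was read as the −log10 q that the authors' peak caller gave against the input. This reading rests on the values: the lowest score was 1.31, and a q of 0.05 corresponds to 1.30. The score belongs to its own list and was used to describe, rank and filter summits within that list. Percentiles of the scores are given list by list, and no difference in score between lists is read as a difference in binding.

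Positions were converted to 1-based coordinates, and summits on chromosomes 1 to 22 and X were kept. Summits of the 4 libraries were pooled and chained into regions wherever neighbouring summits lay at most 200 bp apart. A library was counted as present in a region if it had at least 1 summit there. Pairs of libraries were compared by the Jaccard index (regions present in both libraries divided by regions present in either) and by the percentage of summits of one library with a summit of the other within 200 bp. The chance level of that percentage was measured after moving the first list by 50 kb. Each list was also divided into 10 equal classes by score. A region was called group-specific if both libraries of a group, and neither library of the other group, had a summit in it, and isolated if the nearest summit of the other group lay over 5 kb away. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

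Group values are means ± SD over 2 libraries. Differences between groups were tested with an exact two-sided permutation test over the 4 libraries, whose smallest possible p with 2 against 2 is 0.333, so no comparison here can pass a threshold of 0.05. Counts of group-specific regions were therefore set beside those given by the other 2 ways of dividing the 4 libraries into pairs. Regions are not replicates, and no p was computed across them. Intervals for single-library percentages are exact Clopper-Pearson intervals at 95% and cover counting error only. Summit lists hold no read numbers, so the sequencing depth of each library is unknown and the number of summits also varies with depth and enrichment. The labels do not say whether replicates came from separate cultures, so the spread between them may be technical. Without peak widths or signal, the lack of a summit at a position is not the lack of SMAD2 there: the files hold 1 position for a stretch of enrichment of unknown width.

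The overlap code was tested on simulated data: 4 lists were built from the 23476 regions present in all libraries, with 200 regions added to each group alone and positions scattered with an SD of 30 bp. The added regions were placed in both lists of their group at every detection rate, so finding 200 of 200 tests the overlap code and not the sensitivity under incomplete detection. With each unchanged region detected in 100% of lists, it called 200 regions for each group. At 70% detection it called 1229 regions for the palbociclib group and 1233 for the activin group, each count including the 200 added. Incomplete detection by itself therefore yields group-specific regions. The simulation applied the same detection rate to every shared region, so its counts give no scale for the observed numbers. The number of group-specific regions is thus a description of these lists.

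The rule for named regions was fixed before the data were examined. It took the 15 regions present in all 4 libraries with the best worst rank, and the 15 regions of each group-specific set chosen likewise. Alternatives fixed at the same time were a minimum score of 2 or 5, all contigs, lists of equal length (each library's highest 51535 summits), the highest 10000 and 1000 summits, chaining gaps of 100, 500 and 1000 bp, a replicate block and leaving out each library. Isolation distances and counts per 100-kb window were added after seeing the data. Where lists were trimmed to equal length, up to 2041 summits of a list were tied at the lowest score kept and were taken in order of position. Distances to genes, the 9 gene lists and the 11 sequence motifs that had been planned were not analysed here, because the gene table used here is on GRCh38 and coordinates of different builds were not mixed. Regions are therefore named by hg19 coordinates.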

Results

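SMAD2 is a transcription factor activated by activin A, a ligand of the TGF-β family. Its binding sites were mapped by ChIP-seq in T47D, a human luminal breast cancer cell line that expresses the estrogen receptor. Cells received activin A at 50 ng/ml for 1.5 h, either alone (2 libraries) or after palbociclib at 1 µM for 24 h (2 libraries). Palbociclib inhibits the cyclin-dependent kinases CDK4 and CDK6, which drive entry into S phase. The comparison asks whether the inhibitor alters where SMAD2 is found on the genome after activin stimulation. No library of cells without activin was analysed, so the values describe activin-treated cells throughout.

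More SMAD2 summits were listed after palbociclib. The activin libraries held 51535 and 54243 summits on chromosomes 1 to 22 and X, or 52889 ± 1915 (SD, n = 2). The palbociclib libraries held 62960 and 65207, or 64084 ± 1589 (SD, n = 2), which is 1.21-fold as many. The difference of 11195 summits exceeded the SD of either group, and both palbociclib lists were longer than both activin lists. The exact permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Within each list, the median score was 9.46 and 8.34 in activin replicates 1 and 2, and 9.41 and 8.39 in palbociclib replicates 1 and 2. The 90th percentile of the score was 64.7 and 62.6 in the activin lists and 83.4 and 75.5 in the palbociclib lists. The strongest summit scored 1046 and 1109 in the activin lists and 1319 and 1101 in the palbociclib lists. Scores and numbers of summits both vary with read depth, which is unknown for these lists.

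The 15 strongest regions shared by the libraries ranked within the first 25 summits of every list. Chained summits gave 115321 regions, of which 23476 (20.4%) held a summit in every library and 58548 (50.8%) in a single library. In the shared regions, the summits of the 4 libraries spanned a median of 76 bp. The region on chromosome 17 at 41438551 to 41438576 ranked 2nd in both activin lists and 1st in both palbociclib lists. The region on chromosome 11 at 62609004 to 62609067 ranked 1 and 3 in the activin lists, and 2 and 3 in the palbociclib lists. The region on chromosome 12 at 120729443 to 120729504 ranked 3 and 1, and then 3 and 2. Next came chromosome 15 at 65597208 to 65597249, with a worst rank of 8, and chromosome 1 at 145382926 to 145382967, with a worst rank of 9. On chromosome 1 the region at 149223890 to 149223945 had a worst rank of 12. Of the 15 strongest shared regions, 5 lay on chromosome 1 and 4 on chromosome 17. They included neighbours on chromosome 17: the regions starting at 41438551 and 41445307 lay 6.73 kb apart, and those starting at 56736522 and 56756975 lay 20.4 kb apart. The remaining ones lay on chromosome 11 at 120107436, chromosome 3 at 186501403, chromosome 2 at 122288596, and chromosome 1 at 11968388, 210547398 and 45187382. Whether these loci are highly transcribed, such as small nuclear RNA genes, or enriched without SMAD2 was not tested, because no hg19 annotation or control signal was used here.

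By the Jaccard index, libraries of one treatment overlapped slightly more than libraries of different treatments. The Jaccard index was 0.417 between the activin libraries and 0.422 between the palbociclib libraries. The 4 pairs across treatments ranged from 0.391 to 0.400, with a mean of 0.396. The within-group mean of 0.419 thus exceeded the between-group mean by 0.024. The other 2 divisions of the libraries gave −0.012 each. These values are no separate evidence, because the differences over all divisions must cancel. At equal list lengths the excess was 0.014. The index also depends on the lengths of the 2 lists, which differ most across treatments. By the share of summits found again, the 2 groups went opposite ways. Activin summits were found in palbociclib lists at 58.7% to 62.2%, and in the other activin list at 55.1% and 58.0%. Palbociclib summits were found in activin lists at 49.1% to 50.5%, and in the other palbociclib list at 56.3% and 58.2%. Over the 23476 regions found in all libraries, the rank order correlated at a Spearman coefficient of 0.871 between activin libraries and 0.905 between palbociclib libraries. Across treatments it ranged from 0.860 to 0.880. These coefficients are across regions, which are not independent replicates.

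**Figure D1:**
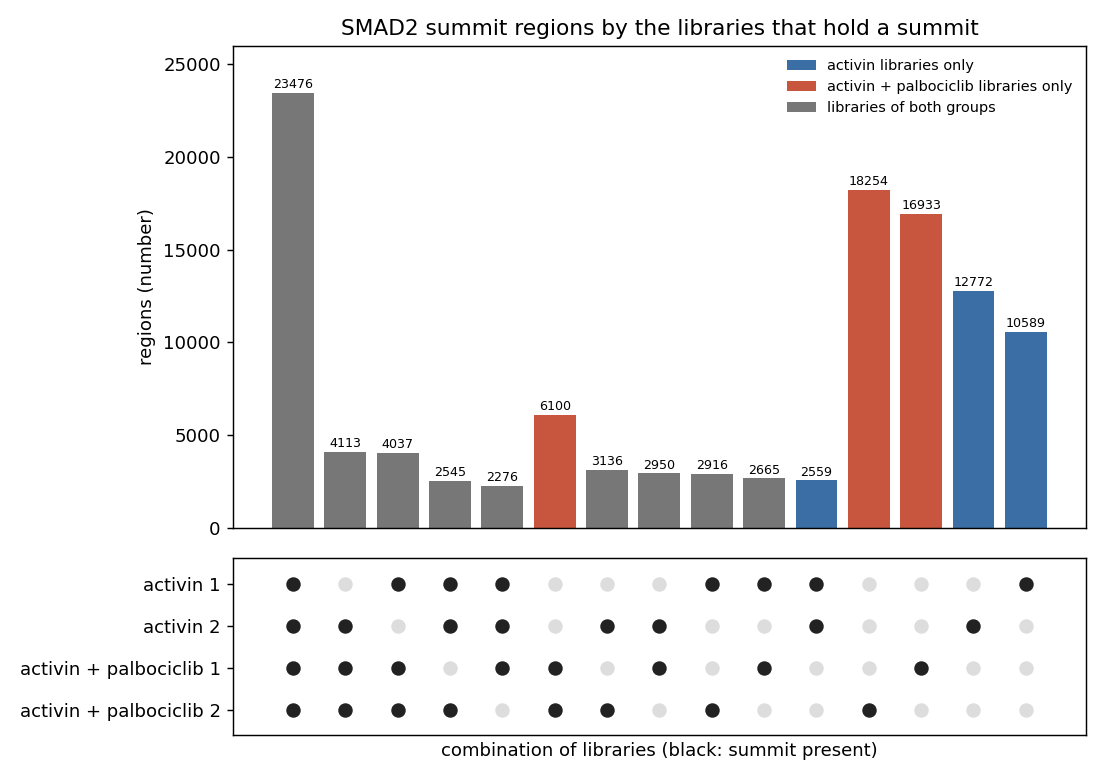
Number of regions (vertical axis, linear) for each combination of libraries that holds a summit, with the combination marked by black dots below each bar. Regions found in all 4 libraries form the tallest bar (23476), and 6100 regions were found in both palbociclib libraries alone against 2559 in both activin libraries alone.

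Regions seen in both palbociclib libraries and in neither activin library were more numerous than the reverse. There were 6100 regions with palbociclib only and 2559 with activin only, so 70.4% of group-specific regions lay on the palbociclib side. The 4 pairs that mix treatments had between 2665 and 3136 regions of their own, so the palbociclib pair lay above this range and the activin pair below it. With lists trimmed to equal length the counts became 3564 and 3079, or 53.7% on the palbociclib side, both above the mixed pairs' 2554 to 2678. Trimming kept activin summits down to scores of 1.34 and 2.9 and palbociclib summits only down to 4.87 and 4.8. This unequal cut can itself make activin-only regions, so their rise above the mixed pairs cannot be credited to the treatment. Among each library's highest 10000 summits the split turned, with 446 regions for palbociclib and 499 for activin (47.2%). The palbociclib side was 39.2% and 42.7% without activin replicates 1 and 2, and 83.5% and 82.1% without palbociclib replicates 1 and 2, because a group left with 1 library needs a summit in that library only.

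Most group-specific regions had a weak summit in at least 1 list, as did most regions of each mixed pair. Of the 6100 palbociclib-only regions, 5323 (87.3%) lay in the lower 5 of 10 score classes of at least 1 list. The median distance to the nearest activin summit was 943 bp, and 1626 (26.7%) were isolated by over 5 kb. Of the 2559 activin-only regions, 1893 (74.0%) lay in the lower classes, the median distance was 506 bp, and 327 (12.8%) were isolated. Mixed pairs gave 383 to 679 isolated regions. Taking the worse of 2 lists makes the lower score classes likely by itself. The median worst class was 8 for both group-specific sets, for each mixed pair and for regions of each single library. Of the regions in the strongest class of both lists of a group, 45 were palbociclib-only and 53 activin-only, and 0 of either set were isolated. In the mixed pairs, regions in the strongest class of both lists numbered 23 to 45. Isolation is rare by itself: 84.1% to 85.8% of all palbociclib summits had an activin summit within 5 kb, and 90.3% to 91.4% of all activin summits a palbociclib one. In the strongest class these means were 99.97% and 99.92%, so the lack of isolated strong regions says nothing specific about them.

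The strongest group-specific regions of the 2 treatments paired up on chromosome 5. The palbociclib-only region at 172741468 to 172741624 ranked 69 and 60 in its lists, with scores of 532 and 490. The activin-only region at 172742728 to 172742841 ranked 145 and 69, with scores of 292 and 387, and lay 1104 bp away. Similar pairs lay on chromosome 7, with palbociclib summits from 5553375 and activin summits from 5553927, and on chromosome 10, with palbociclib summits from 58121282 and activin summits from 58120973. Other palbociclib-only regions were on chromosome 20 at 47663407 to 47663440 (ranks 559 and 464, 538 bp from the nearest activin summit) and at 18488554 to 18488592 (ranks 1221 and 1069, 474 bp). On chromosome 6 they lay at 32163241 (631 bp) and 3069328 (249 bp). On chromosome 11 they lay at 85339303 (280 bp) and 90646468 (539 bp). The rest of the 15 had distances of 262 to 791 bp. The other activin-only regions were led by chromosome 11 at 1760711 to 1760779 (ranks 278 and 344, 1056 bp from the nearest palbociclib summit). They also included chromosome 6 at 26250824 (366 bp), chromosome 1 at 173831821 (2945 bp), chromosome 8 at 102479515 (442 bp) and chromosome 17 at 38478694 (548 bp). Within 1 kb of a summit of the other treatment lay 14 of the 15 palbociclib regions and 12 of the 15 activin regions. Such nearness is no trait of these regions. Of all activin summits in the strongest score class, 99.2% had a palbociclib summit within 1000 bp (mean over 4 pairs of libraries).

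**Figure D2:**
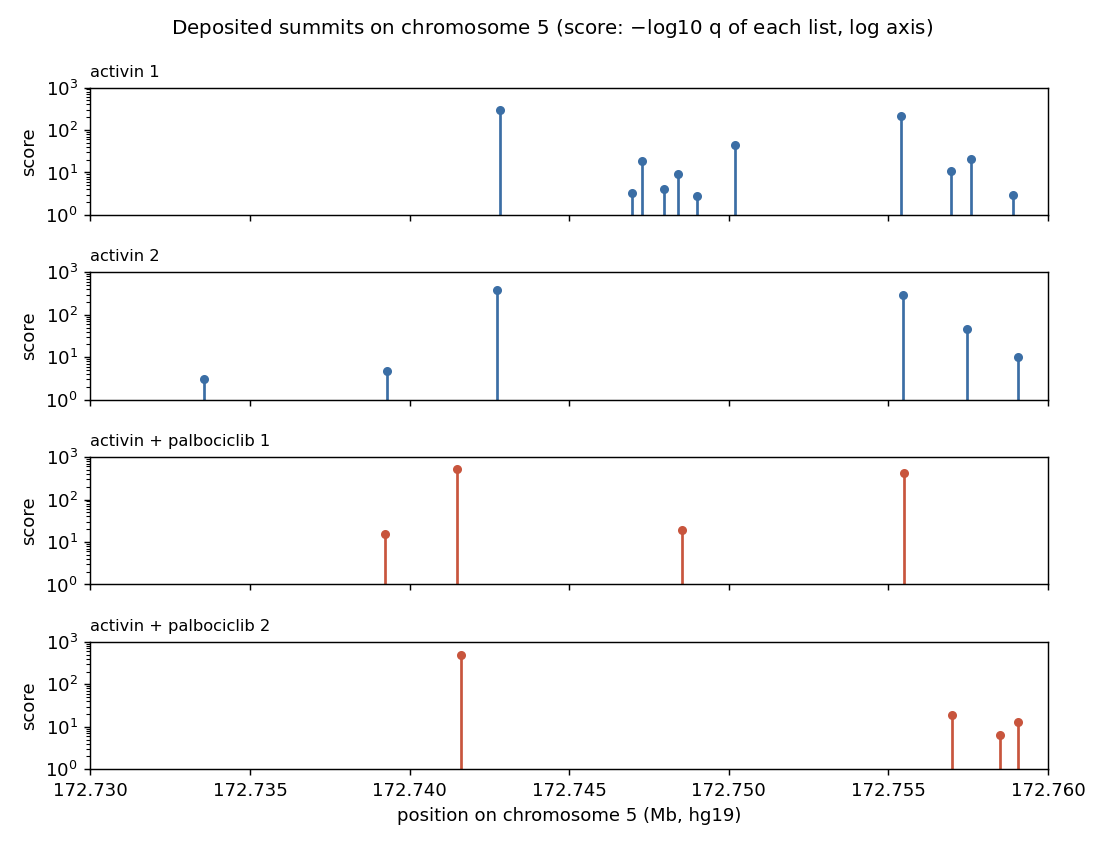
Deposited summits on chromosome 5 from 172.73 to 172.76 Mb (hg19, horizontal axis), 1 panel per library, with the score of each summit on a log axis. The strongest activin summits lie at 172742841 and 172742728 and the strongest palbociclib summits at 172741468 and 172741624. Palbociclib replicate 2 lists no summit near 172755478, where palbociclib replicate 1 scored 417.

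How often a summit was found again depended on its rank. Of activin summits in the strongest class, 94.2% ± 0.3 (SD over 4 pairs of libraries) had a palbociclib summit within 200 bp, and 94.8% ± 0.2 (2 directions) had one in the other activin library. In the weakest class these values were 29.2% ± 2.8 and 21.8% ± 4.7. Palbociclib summits of the strongest class were found in activin lists at 94.3% ± 0.6 (4 pairs) and in the other palbociclib list at 94.4% ± 0.4 (2 directions). In the weakest class, 15.6% ± 0.8 were found in activin lists and 24.8% ± 0.8 in the other palbociclib list. Pairs that share a library are not independent. Over all ranks, activin replicate 1 summits were found in activin replicate 2 at 58.0% (95% interval 57.6 to 58.5) and in palbociclib replicate 1 at 61.2% (60.7 to 61.6). Palbociclib replicate 1 summits were found in activin replicate 1 at 50.0% (49.6 to 50.3) and in palbociclib replicate 2 at 58.2% (57.8 to 58.6). Lists moved by 50 kb matched at 2.13% to 2.83%. Longer lists offer more positions to match, and the palbociclib lists were the longer ones.

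**Figure D3:**
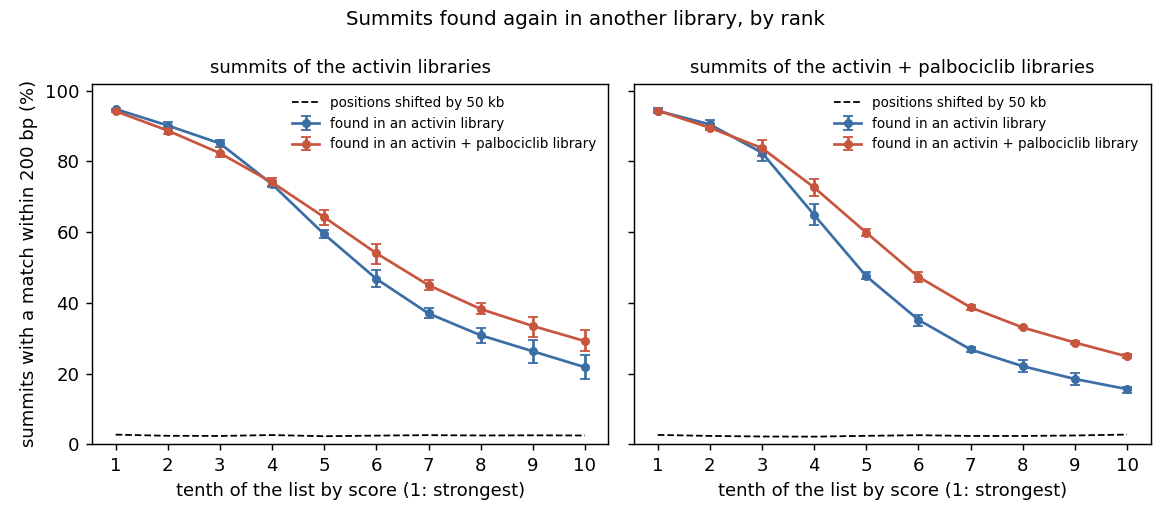
Percentage of summits with a match within 200 bp in another library (vertical axis) for each of 10 score classes, strongest on the left; points are means over pairs of libraries and bars run from the lowest to the highest pair. Matching falls from about 94% in the strongest class to between 15.6% and 29.2% in the weakest, well above the dashed line for lists moved by 50 kb.

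Mean summit density was higher after palbociclib on each of the 23 chromosomes. Density, counted per Mb between the first and last summit of a chromosome, was 1.17-fold as high on chromosome 18 and 1.27-fold on chromosome X, the lowest and highest ratios of the 23 chromosomes. The palbociclib lists were 1.21-fold as long, and the same span divided both groups. These ratios therefore largely restate the list lengths. Density was highest on chromosome 19, at 51.7 ± 4.4 summits per Mb with activin and 62.9 ± 2.7 with palbociclib. On chromosome 17 it was 43.8 ± 2.0 and 51.2 ± 1.9, and on chromosome 22 it was 34.0 ± 2.7 and 41.9 ± 1.4. It was lowest on chromosome X, at 7.46 ± 0.37 and 9.44 ± 0.09 (SD, n = 2 for each). Chromosomes 17, 19 and 22 are known to be rich in genes. Neither gene content nor the copy number of each chromosome in this cell line was set against these densities. The share of summits on chromosome 17 was 6.71% ± 0.06 with activin and 6.46% ± 0.08 with palbociclib, the largest difference in share at −0.245 percentage points. Chromosome 16 held 4.59% ± 0.05 and 4.45% ± 0.08, and chromosome X held 2.14% ± 0.03 and 2.24% ± 0.03. The shares of the groups did not overlap on 11 chromosomes (6 higher and 5 lower with palbociclib), where chance gives 7.67 of 23. The lowest exact permutation p was 0.333, or 0.697 after Benjamini-Hochberg adjustment over 23 chromosomes.

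**Figure D4:**
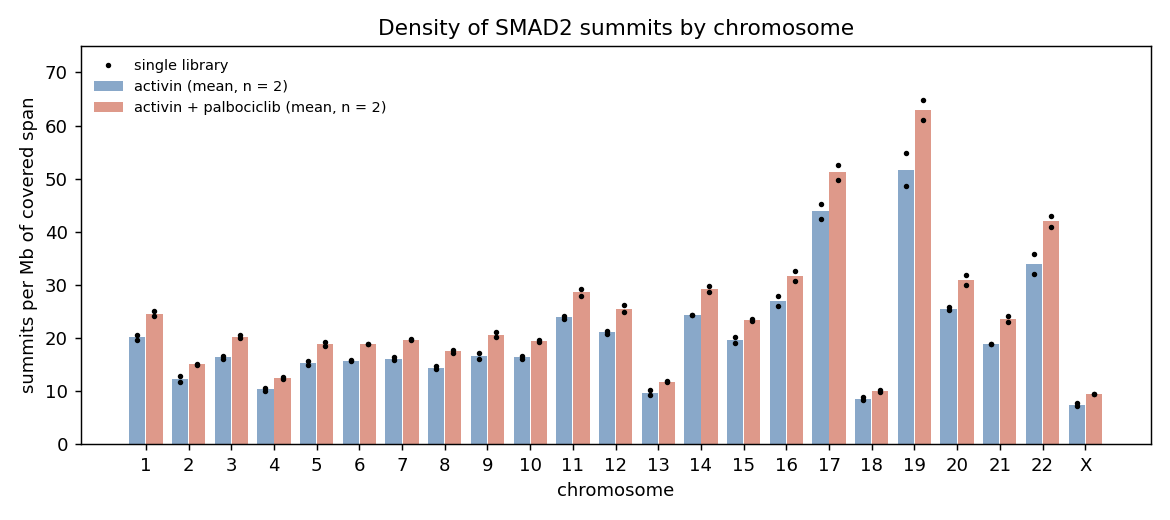
Summits per Mb of covered span (vertical axis) on each chromosome; bars are group means of 2 libraries and dots are single libraries. Density is highest on chromosome 19 and lowest on chromosome X in both groups. The palbociclib lists were longer, and their mean lies above the activin mean on each chromosome.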

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

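Summits on chromosome Y lay outside the main comparisons and entered only the alternative with all contigs. Activin replicates 1 and 2 listed 5 and 5 of them, and palbociclib replicates 1 and 2 listed 12 and 13, and no control library gave a level to set them against. They formed 18 regions, of which 10 were found in 2 or more libraries and 3 in all 4. The strongest lay at 21154586, 21154575, 21154597 and 21154587 in these libraries, with scores of 46.1, 47.9, 110 and 88.6. These positions are given as listed on hg19. Whether the DNA behind them came from chromosome Y at all, and whether it was bound by SMAD2, was not tested.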

How the results depend on the processing

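The isolation distances and the counts per 100-kb window were chosen after seeing the data. The direction of the number of summits (log2 difference 0.277) was kept under all 8 alternatives, at 0.240 to 0.314 without each library in turn. Both palbociclib lists were longer than both activin lists, so neither leaving out a library nor the replicate block could have turned it. The direction of the overlap difference (0.024) was kept under all 14 alternatives. That difference was 0.020 to 0.030 without each library, 0.014 at equal list lengths, 0.014 with a gap of 100 bp and 0.044 in the top 1000. For regions found in both palbociclib libraries alone (6100) and in both activin libraries alone (2559), the counts were 3564 and 3079 at equal list lengths, 446 and 499 in the top 10000 summits, and 62 and 69 in the top 1000. The palbociclib side then held 47.2% and 47.3% in the top 10000 and top 1000, a reversal whose cause was not tested. A gap of 500 bp gave 1439 activin regions, and a gap of 1000 bp gave 3328 and 744. A distance of over 1 kb left 2948 and 658 regions, one of over 5 kb 1626 and 327, and the latter at equal list lengths 1007 and 469. Leaving out each library gave 10176 to 25060 palbociclib regions, 4964 to 15811 activin regions and a palbociclib side of 39.2% to 83.5%. That range follows from the construction, since the group left with 1 library then needs a summit in that library only. Without activin replicate 1 the side was 39.2%, without activin replicate 2 it was 42.7%, without palbociclib replicate 1 83.5% and without palbociclib replicate 2 82.1%. A score of at least 5 gave 4507 and 1823 regions. Same-numbered libraries did not deviate together in rank (correlation of rank deviations −0.052). This gave no sign of pairing by number, but it does not show how the libraries were prepared. With the replicate block, which counts regions of 1 palbociclib library absent from the activin library of the same number, the mean counts were 30702 and 19583, and the overlap difference was 0.024. The strongest class of activin summits was found in palbociclib lists at 87.8%, 97.9% and 99.2% within 100, 500 and 1000 bp, and the weakest at 18.0%, 46.6% and 60.3%. Chromosomes with separate shares numbered 8 with a score of at least 5 and 8 at equal lengths, against 11. Windows of 100 kb higher with palbociclib numbered 3264, and 1486 at equal lengths. Gene distances, gene lists and motifs, planned with their alternatives, were not run for want of an annotation on the files' build, and the unknown read depth limits every count of summits.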

Other observations

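The window counts, the isolation distances and the tests of list length and depth on group-specific and isolated regions were chosen after their results were seen, and the tests on the strongest group-specific regions and on the chromosome 5 window before.

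Counting summits in windows of 100 kb named places where SMAD2 summits were dense or differed between treatments. The densest window was on chromosome 22 from 46.4 to 46.5 Mb, with 51 and 44 summits in the activin libraries and 50 and 57 in the palbociclib libraries. Chromosome 9 from 140 to 140.1 Mb held 37 and 49, and then 53 and 60. The window with the widest gap in favour of palbociclib was on chromosome 5 from 35.1 to 35.2 Mb, with 29 and 26 summits against 50 and 62. Chromosome 10 from 6.2 to 6.3 Mb held 38 and 37 against 55 and 53, and chromosome 12 from 52.6 to 52.7 Mb held 11 and 11 against 24 and 23. In the opposite direction, chromosome 11 from 67.2 to 67.3 Mb held 21 and 18 summits with activin against 9 and 11 with palbociclib. Chromosome 3 from 160.1 to 160.2 Mb held 14 and 16 against 8 and 8. At equal list lengths the chromosome 10 window held 38 and 37 against 41 and 40, the chromosome 12 window 11 and 11 against 17 and 17, and the chromosome 9 window 37 and 48 against 41 and 41. The chromosome 11 window then held 21 and 17 against 9 and 8, and the chromosome 3 window 14 and 14 against 5 and 7. In the full lists, bins of 5 kb that held a summit numbered 9 and 8 against 7 and 7 in the chromosome 11 window. They numbered 6 and 8 against 4 and 5 on chromosome 3, 12 and 14 against 16 and 16 on chromosome 10, and 6 and 7 against 11 and 9 on chromosome 12. The windows named for a difference were picked as extremes, which by itself favours a gap.

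Over 18477 windows, both palbociclib libraries exceeded both activin libraries in 3264 and fell below both in 587. Divisions of the libraries that mix treatments gave 895 to 1139 windows in either direction. At equal list lengths the counts were 1486 and 1240 of 17652 windows, against 990 to 1124 in the mixed divisions. An excess over them appeared in both directions, but the unequal trimming can itself produce the activin side of it. By a gap of at least 5 summits, 131 windows were higher with palbociclib and 5 with activin in the full lists, and 10 and 40 at equal lengths, where trimming had cut the palbociclib lists most.

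Among isolated regions, the strongest with palbociclib only lay on chromosome 6 at 112194627 to 112194687, ranked 15097 and 15579, with the nearest activin summit 165381 bp away. The strongest isolated activin-only region lay on chromosome 19 at 46431248 to 46431250, ranked 4878 and 6516, 25004 bp from the nearest palbociclib summit. Chromosome X held 132 palbociclib-only and 33 activin-only regions, a ratio of 4 and the highest of the 23 chromosomes, while chromosome 17 had the lowest at 1.93. Chromosome X also had the fewest activin-only regions, so its ratio rests on a small count. Mixed pairs were not compared by chromosome.

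The first pattern is the excess of palbociclib-only over activin-only regions, a ratio of 2.38. At equal list lengths the ratio was 1.16, but trimming kept activin summits down to scores of 1.34 and 2.9 and palbociclib summits only down to 4.87 and 4.8, which lowers the ratio whatever the extra summits are, so longer lists cannot be told apart from more binding. For isolated regions the ratio was 4.97, and 2.15 at equal lengths (1007 and 469 regions), where length no longer differs. Dividing the trimmed lists by replicate number gave 2.07 (748 and 361 regions), so other differences between libraries can give such a ratio too. The remaining division gave 518 and 483 regions. The comparison with other divisions was added after the ratios of 2.15 and 2.07 were seen. Different sequencing depth or enrichment cannot be told apart from the treatment, because 0 of the 4 files used here hold read numbers. A larger number of bound sites after palbociclib, the biological explanation the design offers, stays open and untested.

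The second pattern is the group-specific regions in the strongest class of both lists, 45 with palbociclib and 53 with activin. Mixed pairs gave 23 to 45, so such regions also arise without a difference in treatment. If such a region is a summit that moved within, or merged into, a neighbouring strong peak, most should have a strongest-class summit of the other treatment within 5 kb in both libraries. This held for 74.5% of them (27 of 45 and 46 of 53), against 5.68% of equally strong regions found in all libraries when their own summits were left out. That reference counts a second strong summit near a shared region, and mixed pairs were not compared. Nearness within 5 kb does not tell a moved summit from a separate neighbouring one. For the palbociclib regions alone the share was 60.0%. Its 95% interval of 44.3 to 74.3 includes the bound of 50%, but it covers counting error only, and regions are not replicates. Shifts of the reported summit remain a candidate explanation for strong group-specific regions, which these shares cannot decide. A real shift of SMAD2 within these places was left untested.

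The third pattern is the window on chromosome 5 from 35.1 to 35.2 Mb. The lowest palbociclib library occupied 3 more bins of 5 kb than the highest activin library (11 and 12 bins with activin, 15 and 18 with palbociclib), which had been set beforehand to count against a single wide peak split into more summits. That bound was wrong, since longer lists fill more bins and a domain already spread over 11 bins can gain bins by splitting, so splitting cannot be told apart either. Longer lists cannot be told apart from the treatment: at equal lengths the counts were 29 and 22 against 30 and 38, and the groups were parted by 1 summit, between the bounds set beforehand. The window was picked as the most extreme of 18477, which by itself favours a gap, and an effect of palbociclib on SMAD2 there stays open and untested.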
